A study of Mus musculus with 6 samples.

How the data were processed

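RNA-seq was measured in lungs of 6 mice that had eaten a high fat (western) diet for 10 weeks. The labels place 3 libraries in a wild type group and 3 in a Cyp1b1 knockout group, and each group holds 2 females and 1 male. CYP1B1 is a cytochrome P450 enzyme that oxidises steroids, retinoids, fatty acids and polycyclic hydrocarbons. Each library carries its own identifier in the labels, which do not say in words that each came from a separate animal, so p-values measure the spread between these libraries. Replicate numbers 1 to 3 only name the libraries within a group; replicate 3 is the male in both. The text writes "labelled wild type" and "labelled knockout" throughout, because Cyp1b1 was higher, not lower, in the libraries labelled knockout.

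The deposited values are CPM (counts per 1000000 reads assigned to genes) per gene, 1 column per library, for 21900 genes. Each deposited column sums to 1000000 as rounded, with the 0.0001 that the authors' table adds to every CPM value left in. At that rounding the added 0.0001 does not show in the sum. Per the submitters' processing notes, the genome build was mm10 and the tools were TopHat2 and Partek, without versions or roles; the gene annotation, the filters and the strand setting are not given in the sources used here. Since strand use is not given, reads of overlapping and antisense genes cannot be told apart, and near-identical copies can share or lose reads. A total of 21846 gene identifiers (99.75%) were found in GENCODE release M21, which uses the same build as mm10, and positions come from that annotation.

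The depth was read from the size of the smallest step between low CPM values. It gave 23.9, 20.2 and 23.4 M (1000000) assigned reads for labelled wild type 1, 2 and 3, and 22.3, 27.6 and 25.7 M for labelled knockout 1, 2 and 3. Of the values worth up to 100 reads, between 82.1% and 83.3% per library were whole multiples of that step within 0.05, so whole reads were not recovered and no count model was used. The level worth 3 reads, used as a floor, lay between 0.109 and 0.148 CPM per library; it covers counting error only. The plan made before the data were examined named a count model for a table of counts and limma for normalized values; as the table holds CPM, limma was used.

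Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The main test was limma 3.58.1 (R 4.3.3, variance trend) on log2(CPM + 0.5), with genotype label and sex as additive terms. It took 17382 genes whose mean over the 6 libraries was at least 0.5 CPM. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was the threshold. Fold changes are differences on the log2(CPM + 0.5) scale, labelled knockout minus labelled wild type, which understates changes of low genes. The effect of sex came from the same model, and the difference of the genotype effect between the sexes from an interaction term; with 1 male per label, the spread of that test comes from the females and the lone males are assumed to vary like them. Cyp1b1 also received an exact two-sided permutation test over 20 assignments.

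A set of 55 gene lists (27 of them cell types), with 1045 entries of which 1002 were found in the table (5 under another symbol), was fixed before the data were examined. Lists were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, adjusting over the lists. The lists described singly were picked after their results had been seen. They were lists about AhR targets or substances that CYP1B1 metabolises, lists with small camera p-values, and lists that moved in the male libraries. The circadian clock list is therefore 1 of 55 lists tested. The rule for named genes, also fixed beforehand, took Cyp1b1, sex-linked genes, up to 12 genes per direction by size of change among those past the threshold with a mean of at least 1 CPM, the genes of smallest p up to 12 in total where fewer passed, and from each list up to 4 members past the test or 2 of smallest p. A gene that this rule picked and a clock gene that did not pass are not reported here by name, and no other gene took their place. Only the list members of the lists followed singly are printed, and genes outside the rule are said to have been chosen after their values were seen.

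The whole fit was tested on simulated data: 5 tables with the gene means and depths of these libraries. Each had 200 genes changed between labelled knockout and labelled wild type among 17378 genes tested. Spreads estimated from these libraries were dealt out to genes at random, and genes were drawn independently of one another. Changed genes all had a mean of at least 5 CPM, so the recovery does not cover lower genes. The test recovered 91.3% of 4-fold changes, 23.2% of 2-fold changes and 0.307% of 1.5-fold changes, and 5.76% of its calls were false. Alternatives were pseudocounts of 0.1 and 1, no filter, a filter at a mean of 5 CPM, quantile normalization, median centring, robust variance moderation, no sex term, females alone, leaving out each library and an adjusted p under 0.1. Alternatives chosen after seeing the data were limma-voom on reads estimated from the steps, all those of the clock gene count and those of the interaction.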

Results

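The data are gene-level CPM values of 6 mouse lung libraries after 10 weeks of a high fat diet, 3 labelled wild type and 3 labelled Cyp1b1 knockout, with 2 females and 1 male per label. Depth was between 20.2 and 27.6 M assigned reads per library. Between 15698 and 16221 genes reached 1 CPM. Correlations of log2 values between libraries, taken across genes, which are not independent replicates, ran from 0.945 between the males to 0.986 between labelled wild type 1 and labelled knockout 2. The male labelled knockout stood apart on the principal component with the most variance (38.4%) and the male labelled wild type on the next (32.6%). Sex-linked genes matched all 6 labels: Xist, the RNA that silences an X chromosome, was between 542 and 705 CPM in the 4 females and at 0.479 and 1.63 CPM in the males. Ddx3y, a Y-linked helicase, was without a read in the females and at 107 and 85.9 CPM in the males.

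The targeted gene was higher, not lower, in the libraries labelled knockout. Cyp1b1 (ENSMUSG00000024087, mm10 chromosome 17, 79701537 to 79715061, minus strand) was at 12.5, 19.04 and 18.5 CPM in labelled wild type 1, 2 and 3 and at 51.2, 56.1 and 48.4 CPM in labelled knockout 1, 2 and 3. The means were 16.7 ± 3.64 (SD, n = 3) and 51.9 ± 3.92 CPM (SD, n = 3), a log2 difference of 1.63 with a standard error of 0.18, or 3.10-fold. All 3 libraries of one label lay above all 3 of the other, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. In limma over all genes the adjusted p was 0.0588, outside the threshold; over the alternatives it ran from 0.0197 to 0.683. A per-gene CPM does not show which exons the reads came from, so a transcript of an altered gene counts in full. Every direction given for genotype below rests on these labels, which the level of Cyp1b1 does not bear out and cannot refute.

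**Figure D1:**
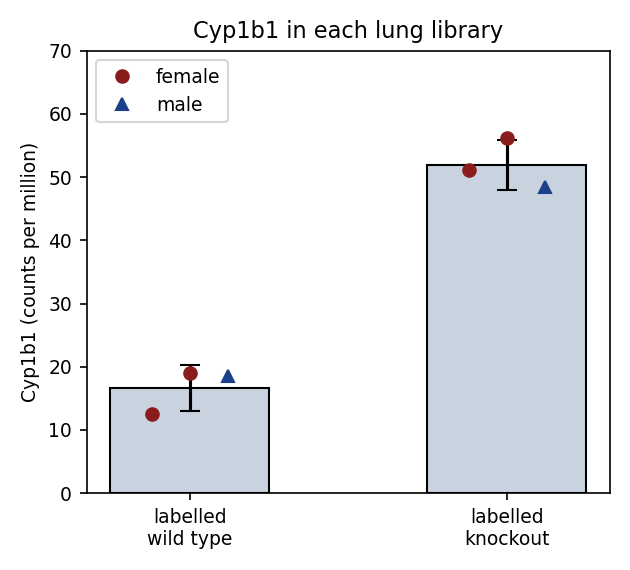
Cyp1b1 in CPM (vertical axis) in each lung library by genotype label; points are libraries (circles female, triangles male), bars are means and error bars SD (n = 3 per label). The libraries labelled knockout lie between 48.4 and 56.1 CPM, above those labelled wild type, between 12.5 and 19.04 CPM.

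The comparison of genotype, made in mice that all ate a high fat diet, found 2 genes past the threshold, both predicted genes that were lower in the libraries labelled knockout. Gm47283 (ENSMUSG00000096768), annotated on chromosome Y from 90784738 to 90816464, was at 88.2 ± 15.5 CPM (SD, n = 3) in the libraries labelled wild type and at 0.362 ± 0.288 CPM (SD, n = 3) in those labelled knockout. Its log2 fold change was -6.72 (SE 0.26, limma adjusted p = 8.04e-05). It had 88.8 and 103 CPM in the females labelled wild type and 72.4 CPM in the male of that label. Its reads therefore did not come from chromosome Y alone. Which other place gave them was not tested, and its level is uncertain because copies elsewhere can share them. Gm16867 (ENSMUSG00000093954, chromosome 14, 69363504 to 69503362) was at 9.55 ± 2.50 CPM (SD, n = 3) in the libraries labelled wild type and below the 3-read floor in each of the 3 labelled knockout, at least 71.0-fold lower against the highest floor among them (limma adjusted p = 0.00603). Its position overlaps that of Entpd4, so reads can be shared there too. Gm16867 missed the threshold without labelled wild type 1, without labelled wild type 2 and without labelled knockout 2, each of which left 1 call. Of the 17382 genes tested by limma, 892 (5.13%) had an unadjusted p under 0.05, of which 313 were higher and 579 lower in the libraries labelled knockout; after median centring these were 596 higher and 335 lower. The 2 labels did not overlap for 1655 genes (9.52%), where chance gives 10%.

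Of the 10 further genes with the smallest p, none passed the threshold. Dbp, a clock-controlled transcription factor of the PAR bZIP family, was at 174 ± 34.5 CPM (SD, n = 3) in the libraries labelled wild type and 56.4 ± 22.4 CPM (SD, n = 3) in those labelled knockout (log2 fold change -1.67, SE 0.18, limma adjusted p = 0.0508). The long noncoding gene Gm42031 was at 0.815 and 12.6 CPM (log2 fold change 3.34, limma adjusted p = 0.0508), and the processed pseudogene Gm6969 at 1.16 and 7.99 CPM (2.37, limma adjusted p = 0.0897). Fundc1, a mitophagy receptor of the outer mitochondrial membrane, was at 34.8 ± 5.04 and 67.6 ± 6.15 CPM (limma adjusted p = 0.0588). Cd59a, a membrane inhibitor of complement, was at 15.0 and 36.0 CPM (limma adjusted p = 0.136), and Camk2b, a calmodulin-dependent kinase subunit, at 7.54 and 19.8 CPM (limma adjusted p = 0.202). Lower values in the libraries labelled knockout were listed for Qpct, a glutaminyl cyclase (10.2 and 2.85 CPM), Fank1 (9.78 and 3.16 CPM) and Tcap, a sarcomere protein (70.9 and 42.3 CPM), with limma adjusted p between 0.242 and 0.282. Dbp and Gm42031 passed with no filter, quantile normalization, median centring, robust moderation and in the 4 females, while the limma adjusted p without labelled knockout 2 was 0.588 for both. It was 0.438 for Dbp without the sex term, and for Gm42031 0.292 without labelled knockout 1 and 0.168 with limma-voom.

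The circadian clock list held the most single members past limma adjusted over a list alone, 13 of 19 measured, with 0 past over all genes; 2 other lists held 1 such member each. Npas2, Arntl and Clock, which form the activating arm of the clock, and Nfil3 rose in the libraries labelled knockout. Dbp, Tef and Hlf of the PAR bZIP family, the period genes Per2 and Per3, the REV-ERB genes Nr1d1 and Nr1d2, and Bhlhe40 and Bhlhe41 fell. Arntl was at 7.65 ± 2.71 CPM (SD, n = 3) in the libraries labelled wild type and 14.6 ± 4.72 CPM (SD, n = 3) in those labelled knockout, and Npas2 at 4.72 ± 0.654 and 11.3 ± 3.17 CPM. Nr1d1 was at 299 ± 76.3 and 192 ± 41.7 CPM, and Bhlhe41 at 45.4 ± 8.39 and 23.7 ± 0.754 CPM. Per1 (220 and 217 CPM), Cry1, Cry2, Ciart and Rora were among those that did not pass. Clock genes other than Dbp, Nr1d1, Bhlhe41 and Npas2 lie outside the naming rule and were chosen after their values were seen. All 13 kept their direction under quantile normalization and median centring. The list's median log2 fold change was -0.47, called by camera at the preset correlation (adjusted p = 0.000979) and not with an estimated correlation (adjusted p = 0.751). The count was 8 without labelled wild type 2 and 6 without labelled knockout 2.

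**Figure D2:**
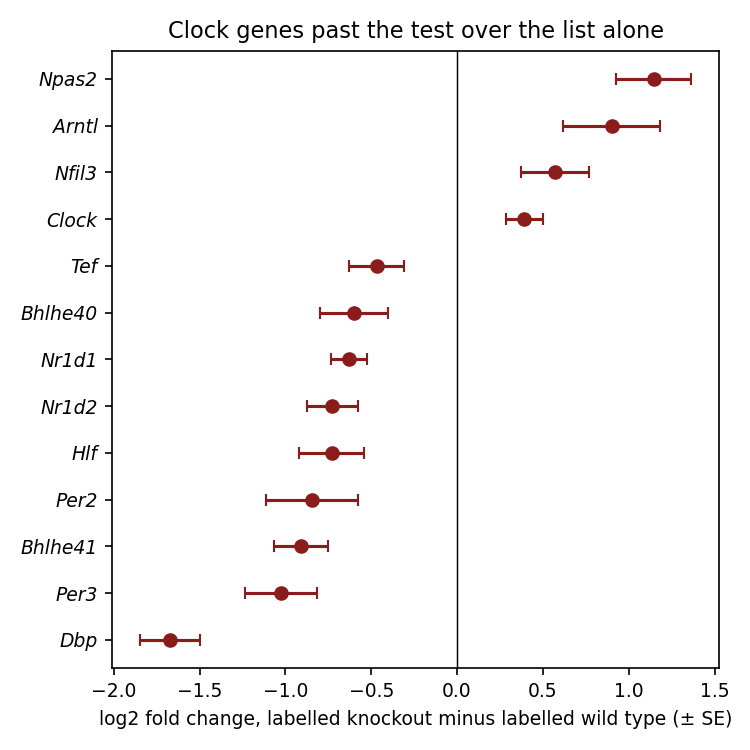
Log2 fold change (horizontal axis, labelled knockout minus labelled wild type) of the 13 circadian clock genes past the test adjusted over the list alone, with standard error bars from limma over 6 libraries. Npas2, Arntl, Nfil3 and Clock lie above 0, and 9 genes from Tef down to Dbp lie below it.

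Lists about AhR targets and about what CYP1B1 and related enzymes metabolise showed no member past limma over all genes or adjusted over the list alone. The AhR list was fixed without Cyp1b1 and holds Ahr itself, so its median leaves Cyp1b1 out. The 10 AhR target genes measured had a median log2 fold change of -0.03 (camera adjusted p = 0.715), the 15 retinoid genes -0.02 (0.718), the 14 steroid and estrogen genes 0.02 (0.598) and the 19 eicosanoid genes -0.07 (0.953); the first, the retinoid and the eicosanoid medians changed sign under quantile normalization or median centring. Camera's direction was up for AhR, retinoid and eicosanoid genes although their medians were below 0. Ahr itself was at a log2 fold change of -0.28, Ugt1a6a at 0.32, Cyp26b1, an enzyme that degrades retinoic acid, at 0.90, Rarg at -0.28, Hpgd at 0.49 and Ptges at -0.29, each with a limma adjusted p of at least 0.775. The lists of xenobiotic P450s (median 0.14, adjusted p = 0.00301), fatty acid and triglyceride synthesis (0.15, 0.00131) and cholesterol biosynthesis (0.06, 0.0164) were called higher by camera, and each call ended with an estimated correlation (adjusted p = 0.751). The 3 calls also ended in the 4 females, with medians of 0.016 for xenobiotic P450s (camera adjusted p = 0.632, direction turned to lower), 0.0043 for fatty acid and triglyceride synthesis (0.587) and -0.0064 for cholesterol biosynthesis (0.846). In these, Acaca, which makes malonyl-CoA, was at 47.8 ± 6.82 and 67.7 ± 3.20 CPM and the desaturase Scd1 at 1360 ± 226 and 1903 ± 57.3 CPM (SD, n = 3 each), both outside the threshold (limma adjusted p = 0.775). Cyp2d22 and Idi1 had log2 fold changes of 0.41 and 0.18 and Cyp4a12b was at 4.48 and 8.82 CPM. These did not pass either. Cyp4a12b was uneven within the label, at 0.921, 8.21 and 4.31 CPM in labelled wild type 1, 2 and 3.

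Neutrophil, antigen presentation and interferon lists gave the 3 smallest camera p-values, and the immune, blood and cell cycle lists described here followed the 2 male libraries. Camera at the preset correlation called 25 of 55 lists (14 higher, 11 lower in the libraries labelled knockout); with an estimated correlation 0 were called (adjusted p of at least 0.633), and fry's directional test called 0 (adjusted p of at least 0.774). Neutrophil markers were higher (median log2 fold change 1.39, adjusted p = 1.38e-10, and 0.751 with an estimated correlation), as were platelet (0.38, 0.00198) and erythroid markers (0.33, 0.000848). Antigen presentation genes (-0.88, 1.00e-05), interferon-stimulated genes (-0.63, 1.00e-05), plasma cell (-1.12, 0.000848), B cell (-0.48, 0.0028), T cell (-0.48, 0.00301) and dendritic cell markers (-0.50, 0.000755) and cell cycle genes (-0.39, 0.000848) were called lower, each with an adjusted p of 0.751 with an estimated correlation. No member of these lists passed limma over all genes; Il1r2 and Trem1 (neutrophil; log2 fold changes 1.96 and 1.05), Ifit3 and Ifi27l2a (interferon; -0.71 and -0.84), H2-DMb1 and H2-Aa (antigen presentation; -0.82 and -1.15) and Derl3 and Ighg3 (plasma cell; -1.34 and -1.73) had the smallest p. Within the label, the neutrophil median was 4.27 log2 units higher in the male labelled knockout than in its females, and the antigen presentation median 1.75 higher in the male labelled wild type. Between the females of the 2 labels these medians differed by 0.06 and -0.01. The same 2 males held the lowest and highest mitochondrial shares (3.24% in labelled wild type 3, 5.46% in labelled knockout 3) and the fewest and most genes without a read (893 and 1778). In the 4 females alone 9 lists were called, 5 of them among the 25 and in the same direction, while 11 of the 25 pointed the other way. Platelet markers were among the 11 and were called lower there (median -0.47, camera adjusted p = 5.29e-05). Erythroid markers also pointed lower, without a call (-0.20, camera adjusted p = 0.587).

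**Figure D3:**
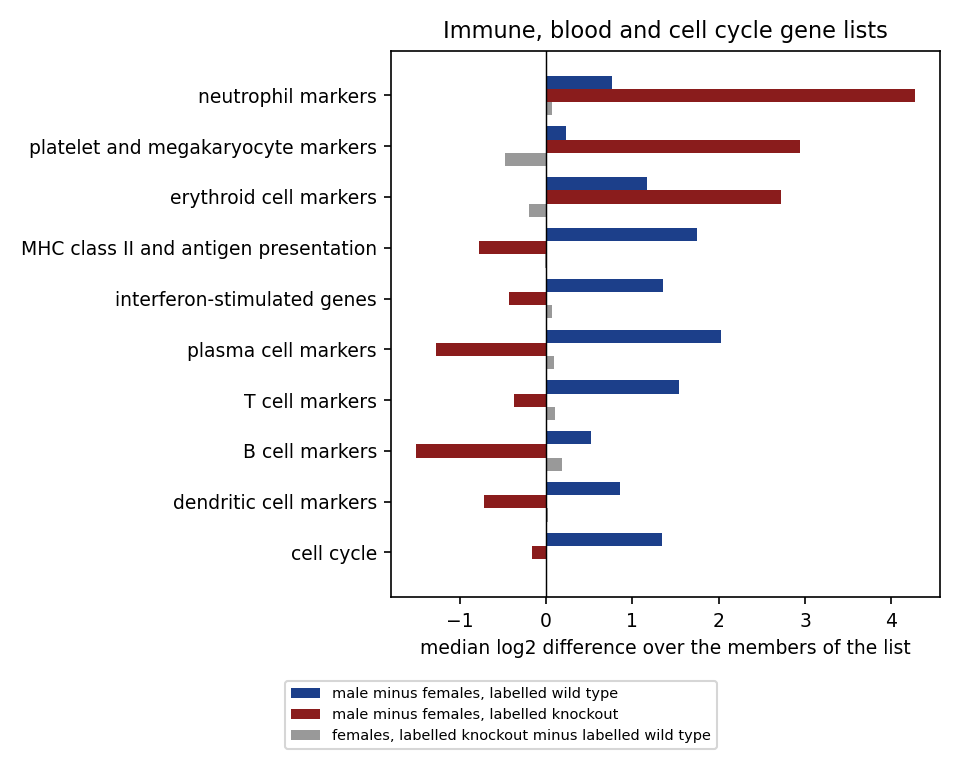
Median log2 difference (horizontal axis) over the members of 9 immune and blood gene lists and the cell cycle list; blue bars compare the male with the 2 females labelled wild type, red bars the male with the 2 females labelled knockout, and grey bars the females of the 2 labels. Neutrophil markers reach 4.27 in the male labelled knockout, and the grey bars lie between -0.47 and 0.19.

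Between the sexes, 145 genes passed limma, 109 higher and 36 lower in males, of which 4 lie on chromosome Y and 7 on chromosome X. Xist, Ddx3y, Eif2s3y, Kdm5d and Uty had the smallest p. Igfbp3, a carrier of insulin-like growth factors, was at 60.1 and 56.6 CPM in the males and between 192 and 205 CPM in the females (log2 difference -1.75, SE 0.10, limma adjusted p = 0.000332). The lectin receptor Clec4e was at 83.2 and 57.3 CPM in the males against 4.35 to 8.54 CPM in the females (limma adjusted p = 0.00103), and the chemokine receptor Ccr2 at 113 and 107 CPM against 34.3 to 46.6 CPM (limma adjusted p = 0.0146). Igfbp3, Clec4e and Ccr2 were chosen after their values were seen. The 2 males are also the libraries that stood apart on the principal components. Sex therefore cannot be told apart here from other differences shared by these 2 lungs. The count fell to 21 without labelled knockout 2, 33 without labelled knockout 1, 68 without labelled wild type 2 and 74 without labelled wild type 1, and rose to 840 or 724 without labelled wild type 3 or labelled knockout 3, which leaves 1 male.

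The genotype difference between the males was not that between the females for 441 genes (limma interaction term; 122 higher and 319 lower in the libraries labelled knockout for males relative to females). All 16 antigen presentation genes measured were among the lower ones and 14 of 18 neutrophil markers among the higher ones. In the male labelled wild type, Gbp2, an interferon-induced GTPase, reached 532 CPM, complement factor Cfb 515 CPM and the immunoglobulin gene Igha 966 CPM, against 39.8, 33.9 and 33.3 CPM in the male labelled knockout. In that library the granule gene Ngp reached 1050 CPM and the platelet chemokine Ppbp 156 CPM, against 4.52 and 18.7 CPM in the male labelled wild type. Gbp2, Cfb, Igha, Ngp and Ppbp were chosen after their values were seen. With 1 male per label, this compares 2 animals beyond the spread of females. The count was 230 without labelled knockout 1.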

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

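The tests of the explanations weighed below, the counts of splits and the clock gene counts were chosen after the results were seen; the interaction term, the scalings, the fit of the females alone and the list tests were planned. The genotype difference differed between males and females, by the interaction term of limma, for 441 genes, among them Hpgd (interaction log2 1.15), Il1r2 (2.92), Trem1 (2.14), H2-DMb1 (-2.02), H2-Aa (-3.15) and Xist (1.21). Each was picked out by a difference between groups, and each rests on 1 male per label. Hpgd, which breaks down prostaglandins, was at 922 CPM in the male labelled knockout and 384 CPM in the male labelled wild type, against 492 to 588 CPM in the females. The Xist value comes from 0.479 and 1.63 CPM in the 2 males.

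Cyp1b1 was higher in the libraries labelled knockout. A difference in depth or scaling is argued against, since the lowest log2 fold change under quantile normalization or median centring was 1.71. An exchange of the 2 genotype labels as a whole cannot be told apart from labels that are right, because no value per exon was analysed here. Under either, a knockout allele would still give reads. The mean was 51.9 CPM in the libraries labelled knockout and 16.7 CPM in those labelled wild type. Both lie above the highest 3-read floor, 0.148 CPM. A biological rise of transcript from a disrupted gene stays open, untested.

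Immune and blood gene lists differed between the genotype labels by camera at the preset correlation, and each of these calls ended with an estimated correlation (adjusted p = 0.751). The values that the 2 male libraries would give as the source are there: of the 17 fixed lists on immune or blood cells and responses, 10 were called over all libraries, and 0 of these in the same direction in the 4 females, against 5 of the 15 other lists called. Blood left in the lung of the male labelled knockout cannot be told apart from a change in its cells: relative to the females of its label, erythroid markers were 2.73 and platelet markers 2.94 higher, with Hbb-bs at 2141 CPM against 441 and 318, while the higher of its B and T cell marker medians was -0.38; in the male labelled wild type erythroid markers were 1.18 higher than in its females, with Hbb-bs at 1008 CPM against 584 and 327. Sex, RNA quality, the state of each animal and how each lung was taken stay open, untested, with 1 male per label. For the number of lists called, 3 against 3 libraries give only 10 splits, too few for a share under 0.05; 4 of the 10 gave as many lists as the real 25, the highest of the others 29.

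The clock gene shift was seen without the males. The 2 male libraries are argued against as its only source. In the 4 females alone, 10 of all 19 clock genes passed limma adjusted over the list alone, and 0 did in either other split of these females. So few splits cannot give a share under 0.05. In the others each side mixes the labels, so a label difference widens the spread and lowers their counts. Clock genes can move together, so the 10 are not separate observations. Lungs collected at different times of day may give such a shift. The Arntl-side genes were taken as Arntl, Npas2, Clock and Nfil3 (median 0.74). The Dbp-side genes were taken as Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per2, Per3, Ciart and Bhlhe41 (-0.75). The medians lay 1.48 apart. Both sides were drawn up after the values were seen, and Per1 and Bhlhe40, among others, were in neither. The Arntl side holds the 4 clock genes that rose past the test, so its sign was settled by that choice. The gap therefore decides nothing about time of day. No collection time was used here, so a difference in time of day cannot be told apart from an effect of genotype. Of the 10 splits of the libraries, 1, the real one, gave 13 or more clock genes, and the highest of the others gave 0; 10 splits are too few for a share under 0.05.

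For the number of genes past the threshold, 1 of the 10 splits, the real one, gave as many as 2, and the highest of the others gave 1; these splits are again too few for a share under 0.05.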

How the results depend on the processing

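Added after seeing the data were limma-voom, all alternatives of the clock count and those of the interaction; the others were planned. The planned count models with their normalizations and filter were not run because the table holds CPM. No paired analysis was possible because the labels carry no number shared between the groups. The count of 2 genotype genes became 3 without a sex term and with a pseudocount of 1, and 2 with a pseudocount of 0.1. It was 6 with no filter (21900 genes tested), 6 with quantile normalization, 6 with median centring and 6 with robust moderation, 7 in females only, 7 at an adjusted p under 0.1 and 1 with a mean of at least 5 CPM, which removes Gm16867. Leaving out 1 library each gave 1 to 4. limma-voom gave 2, sharing 1 gene (Gm47283) and adding Saa3. Under quantile normalization and median centring 3 calls were higher and 3 lower, against 0 and 2; the median log2 fold change of all genes was -0.06 as deposited and 0.05 after median centring. For causes other than the number of genes or libraries, the cause was not tested. Cyp1b1 kept its direction in every alternative, with a log2 fold change of 1.42 to 1.76.

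The 25 lists called became 9 in females only and 9 to 30 leaving out each library, 0 with an estimated correlation and 0 with fry; the fewest came without either male. fry's mixed test called mesothelial markers (adjusted p = 0.0298). The clock count of 13 ran from 6 to 14 leaving out each library, and was 10 to 13 otherwise. The sex count of 145 ran from 21 to 840 leaving out each library, and the interaction count of 441 from 230 to 577 leaving out each female library, since the term cannot be fitted without either male. Over 16 alternatives the 33 named genes other than Cyp1b1 and the sex-linked genes, which were not followed, gave 501 results on the same side of the threshold, 19 that gained it, 4 that lost it and 0 that turned. Only 2 of these genes, Gm47283 and Gm16867, passed in the main fit. Most of the 501 were thus results outside the threshold that stayed outside, and the 4 losses were all of Gm16867. The genes were picked by small p in the same data, so the 0 turns are no support for their directions. For 11 lists followed, 68 results held, 30 lost the call and 12 turned. With a sex term, leaving out either male fits the other exactly, so those 2 alternatives repeat the medians of the females only, and the 12 turns hold 6 distinct values: AhR targets to 0.0075 without labelled wild type 2 and 0.097 without labelled knockout 1 (-0.12 at the lowest, without labelled knockout 2), retinoid genes to 0.036 without labelled knockout 1 (-0.065 without labelled knockout 2), and, in females only and without either male, cholesterol biosynthesis to -0.0064, interferon-stimulated genes to 0.066 and plasma cell markers to 0.095. The last 2 were lowest without labelled knockout 1, at -0.78 and -1.46. Why these turned was, beyond the libraries left out, not tested. No median of a called list turned with scaling, while 15 others of the 55 did. In the simulated tables, changes of 2-fold or less in genes with a mean of at least 5 CPM were mostly not recovered. Lower genes were not tried.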

Other observations

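The hypothesis on chromosome 17 below and its test, and the genes of this part that lie outside the naming rule, were chosen after the values were seen. In the 4 females, Chil3, a chitinase-like protein of alveolar macrophages, was at 279 and 224 CPM in the libraries labelled wild type and 58.4 and 64.5 CPM in those labelled knockout (log2 fold change -2.02, SE 0.13, limma adjusted p = 0.000469), while the males were at 238 and 231 CPM; its interaction passed (limma adjusted p = 0.00408). Alveolar macrophage markers were among the 9 lists called by camera in the females (median -0.13, adjusted p = 0.0319). That list holds Chil3, so it is no separate support for it. Cardiac muscle markers (-0.22, 1.50e-05), platelet markers (-0.47, 5.29e-05) and clock genes (-0.33, 9.28e-05) were also lower in the females labelled knockout. Markers of NK cells (0.34, 0.000585), mesothelium (0.16, 0.00275), nerve and Schwann cells (0.27, 0.00275), glands (0.55, 0.0319) and club cells (0.15, 0.0333) were higher. With an estimated correlation each adjusted p was 0.955. Camera did not call the alveolar macrophage, cardiac muscle and NK lists over all 6 libraries (adjusted p = 0.505, 0.718 and 0.953). NK markers pointed lower there. Over all 6 libraries the glandular list (median 0.66, camera adjusted p = 0.000848, and 0.633 with an estimated correlation) held Lyz1, a lysozyme, at 178 ± 17.9 and 262 ± 38.0 CPM (SD, n = 3), past limma adjusted over the list alone. Tcap passed that test in the cardiac muscle list.

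Nnt, Entpd4, Entpd4b and Ccl21b did not pass limma over all genes. The 2 gene models of Nnt, a mitochondrial transhydrogenase that is disrupted in C57BL/6J mice, had log2 fold changes of 1.09 and 1.43 (limma adjusted p = 0.282 and 0.343). Both are annotated on nearly the same stretch of chromosome 13. Their reads can be shared, so they are not separate measurements. Entpd4, which overlaps Gm16867 on chromosome 14, and Entpd4b had log2 fold changes of -0.71 and -0.81 (limma adjusted p = 0.775 and 0.327). On chromosome 4, Ccl21b, a chemokine with near-identical copies, was at 31.1 and 18.9 CPM (limma adjusted p = 0.671).

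A hypothesis from these values is that a chromosome segment around Cyp1b1 differs between the groups, as a segment carried along with a targeted allele may. Of 108 genes tested within 10 Mb on either side, Cyp1b1 left out, 18 (16.7%) had an unadjusted p under 0.05, against 5.05% elsewhere. Of 2077 windows of the same width along the autosomes and chromosome X, which overlap one another, 0.0963% had as large a share, and the largest was 17.2%. Windows that overlap the tested one were kept and windows with few tested genes were left out. The share is therefore not a rank among separate regions. Of the 18 genes, 10 were lower in the libraries labelled knockout, among them Qpct, the processed pseudogene Gm6548 (12.4 and 5.71 CPM) and Cox7a2l (129 and 96.5 CPM), and 8 were higher, among them Slc8a1 (52.0 and 67.7 CPM). The position of this excess fits a difference at the locus, and it does not tell which of the groups carries an altered allele. None of these genes passed limma over all genes (adjusted p of at least 0.242). Such a segment would not cover Gm16867 and Gm47283, which passed the threshold and are annotated on chromosomes 14 and Y. The labels give no strain, so whether the groups differ in background elsewhere in the genome was not tested.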
